A study of Mus musculus with 2 samples.

How the data were processed

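Cells from the back skin of female mice treated with imiquimod cream were measured as single-cell RNA libraries, with 1 library per genotype (wild type, WT, and Chrna5 knockout, KO). Imiquimod is a Toll-like receptor agonist that causes a psoriasis-like inflammation of mouse skin. Per the labels, 62.5 mg of 5% cream was applied on 6 days and the skin was taken on day 7 from mice aged 6 to 8 weeks. The skin was digested with collagenase and viable cells were sorted by exclusion of a dead-cell dye. The labels give 5 mice per experimental group and do not say whether a library pools several mice. They name both the C57BL/6N and the C57BL/6J substrain. The cream-base control group that the labels mention is not analysed here.

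The deposited values are raw UMI counts per gene and cell barcode, per the file headers, with no normalization. Cell Ranger 3.0.2, Seurat 3.0 and the genome build mm10 are named, per the submitters' processing notes, while the matrix header gives software version 3.1.0. Which barcodes were left out before deposit is not given in the sources used here. Every deposited barcode held at least 500 UMIs. The count table covers 31053 genes. Gene positions come from the GENCODE mouse annotation of the same build, whose release may differ from the one the submitters used.

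From the deposited counts, cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored in each library with Scrublet (in scanpy 1.11.5, expected share 8%). Its own threshold marked 0 of 13938 WT cells and 51 of 10233 KO cells (0.498%), so the caller did not work and most doublets remain. An alternative removed the highest scores, at 0.8% of cells per 1000 barcodes (1623 WT and 891 KO cells). Counts were scaled to 10000 UMIs per cell on a log scale. Both libraries were clustered together with 2000 variable genes chosen per library, 30 principal components, 15 nearest neighbours and Leiden resolution 1, with no batch correction because genotype and library are the same split.

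Markers of 19 cell types were fixed before the data were examined. The rule that turns markers into names was set after the data were seen, and it replaced an earlier rule that failed for keratinocytes. In this rule a gene's level in a cluster is set against its median over clusters, each with 10 CPM added. A cluster takes the type with the highest mean of its 6 highest markers. It needs 3 markers at 2-fold or more in at least 10% of its cells. It also needs a log2 margin of 1.5 over every type of another lineage, and no other type may have more markers among its first 10 genes. Of 35 clusters, 25 were named, in 13 classes, and 10 stayed unnamed. The unnamed clusters held 38.0% of WT and 16.9% of KO cells.

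UMIs were summed per library and class and scaled to the class total of the library (CPM, counts per 10000 UMIs times 100). The ratio of KO over WT has an exact 95% interval conditional on the summed count. Shares have exact 95% Clopper-Pearson intervals, and sums have exact Poisson intervals. All intervals cover counting error only. A gene with 0 UMIs in a library was set against 3 counts. Cells are not replicates, so no test between genotypes was possible and none is given. Values within a class were compared where each library held at least 200 cells of it, which left 5 classes.

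Genes are named by a rule fixed before the data were examined. Among genes with at least 50 UMIs and at least 50 CPM in the higher library, the first 10 each way were taken by the interval bound nearest 1, in the 3 classes with most cells. The first 5 each way were taken in other classes and over all kept cells. Not every gene the rule takes is printed. Mitochondrial, ribosomal, haemoglobin and receptor-segment genes, Xist, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and unnamed gene models were left out. So was a gene whose CPM was under 20% of that in another class of the same library, which could be free RNA. From each list described, the member with the highest CPM and those with the largest ratio each way were also taken.

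For 37 gene lists fixed in advance, the median log2 ratio over members with at least 20 UMIs was given where 5 or more were measured. It was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. A list is called higher or lower where its median has that sign and lies at or beyond percentile 97.5 or 2.5, as a description of these 2 libraries. Members are counted as higher or lower at 1.5-fold or more with an interval that leaves out 1. Cycling cells are those with a UMI of Mki67 or Top2a after each cell was thinned to 600 UMIs, which left out 1071 WT and 109 KO cells.

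The calculations were tested on simulated counts with 200 changed genes. In the keratinocyte simulation over 14956 genes, intervals held the true ratio for 95.3% of unchanged genes, and 97.5% of genes doubled and 80% of genes halved were found in the right direction. In the T cell simulation over 8653 genes these shares were 95.9%, 82.5% and 70%. Of 200 unchanged lists, 10 were called in the keratinocyte simulation and 9 in the T cell simulation. The simulated sums had Poisson error alone, which the intervals assume, and the unchanged lists were random genes. Spread between cells, free RNA, uneven clusters and genes that move together were not simulated. The simulation therefore checks the calculations only, not how far they hold for these libraries.

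Alternatives fixed before the data were examined were a mitochondrial limit of 20%, at least 500 genes per cell, no doublet removal, resolutions 0.5 and 2, and separate clustering of each library. Further ones were median-ratio scaling over genes with at least 50 CPM, thinned cells, equal weight per cell, list members with at least 100 or 1 UMI, 2 UMIs for a cycling cell, unthinned cells, and every barcode for Chrna5. Alternatives chosen after seeing the data were at least 1000 UMIs per cell, removal of the highest doublet scores, shares of named cells, clusters in which each library holds at least 20% of cells, and lists without members that could be free RNA. Tools were Python 3.11.15, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.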

Results

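The data are 2 droplet single-cell RNA libraries of imiquimod-treated mouse back skin, 1 from WT and 1 from Chrna5 KO mice. The WT library held 14557 barcodes and 147260653 UMIs, and the KO library 10886 barcodes and 123839924 UMIs. After filtering, 13938 WT cells (95.8%) with a median of 4603 UMIs and 10182 KO cells (93.5%) with a median of 6331.5 UMIs were kept. Cells under 1000 UMIs made up 16.6% of the WT and 6.17% of the KO cells. With 1 library per genotype, each difference is one between these 2 libraries and has no replicate check. All intervals are 95% intervals of counting error.

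Chrna5 encodes the alpha 5 subunit of nicotinic acetylcholine receptors (ENSMUSG00000035594, chromosome 9, 54980880 to 55007779, plus strand, mm10). It was close to undetected in both libraries. Over all kept cells there were 12 UMIs in WT (0.0822 CPM, 0.0425 to 0.144) and 6 in KO (0.0494 CPM, 0.0181 to 0.107), a ratio of 0.60 (0.185 to 1.73). Keratinocyte-like cells held 8 UMIs in WT and 0 in KO, with an upper bound of the ratio of 0.825. Monocyte and macrophage-like cells held 1 and 3 UMIs. The deleted part of the gene is not given in the sources used here, so these 3' counts do not check the genotype labels. The list of genes next to Chrna5 on its chromosome was not called in any of the 5 compared classes, with a keratinocyte median log2 ratio of 0.14 over 17 members. That list does not hold every gene nearby. Gldn (chromosome 9, 54286486 to 54341786) is not in it and was 3.29-fold higher in fibroblast-like cells of the KO library. Gldn was also among the leading genes of fibroblast-like cluster 30, which held 104 WT and 416 KO cells. Its position and the make-up of the class were not told apart. Genes of this chromosome outside the list were not examined as a set. Nicotinic and muscarinic system genes were measured for 10 members in keratinocyte-like cells, with a median of 0.40 at percentile 95.7, which is not a call. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs in both libraries, whereas Xist was at 488 and 712 CPM. Nnt, which is disrupted in C57BL/6J mice, had 0 UMIs in both.

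Which cell types each library contained was compared first. Fibroblast-like cells made up 17.7% (17.1 to 18.4) of WT and 28.0% (27.1 to 28.9) of KO cells. T-like cells made up 1.91% (1.69 to 2.15) and 6.22% (5.76 to 6.70). Keratinocyte-like cells were 27.9% (27.2 to 28.7) and 26.1% (25.3 to 27.0), and monocyte and macrophage-like cells 8.08% (7.63 to 8.54) and 8.64% (8.10 to 9.21). Among rarer classes, Schwann-like cells were 0.452% and 2.73%, pericyte and smooth muscle-like cells 0.466% and 2.14%, and vascular endothelial-like cells 0.617% and 2.22%. Lymphatic endothelial-like cells were 0.646% and 1.44%, melanocyte-like cells 1.03% and 1.46%, and Langerhans-like cells 0.301% and 0.501%. Hair follicle and sebaceous gland-like cells were 2.40% and 2.91%, mast and basophil-like cells 0.395% and 0.471%, and adipocyte-like cells 0.0861% and 0.236%. No cluster was neutrophil-, dendritic-, NK- or B-like. Neutrophil markers summed over all cells stood at 289 CPM in WT and 270 CPM in KO, but they were not specific to neutrophils, with 918 and 815 CPM in monocyte and macrophage-like cells. The list of neutrophil maturation and activation genes had a median log2 ratio of -0.97 over all kept cells, with 13 of 20 lower and 3 higher. This list was not specific to neutrophils either. Its member Chil3 stood at 741 CPM in WT monocyte and macrophage-like cells, and Lcn2 at 476 CPM in WT keratinocyte-like cells. T cell markers were at 75.7 and 137 CPM.

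Unnamed cells, whose share differed between libraries (38.0% and 16.9%), set part of these shares. As a share of named cells, keratinocyte-like cells were 45.0% in WT and 31.5% in KO, fibroblast-like cells 28.6% and 33.7%, monocyte and macrophage-like cells 13.03% and 10.4%, and T-like cells 3.08% and 7.48%. The keratinocyte ratio of 0.937 was 1.45 with each library clustered on its own. The dead-cell sort and the depth gap between libraries can also set shares. Vascular endothelial-like cells were led by Iigp1 and Rsad2, which themselves differed between the libraries.

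**Figure D1:**
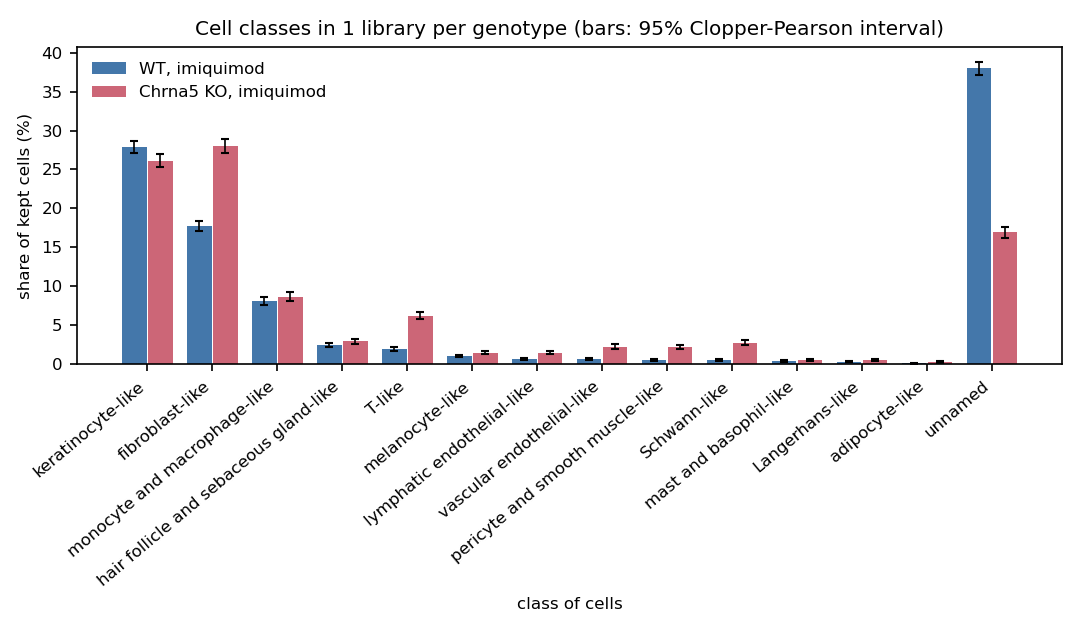
Share of kept cells (%) in each class for the WT (blue) and Chrna5 KO (red) library, with exact 95% Clopper-Pearson intervals of counting error as error bars. Fibroblast-like cells stand at 17.7% and 28.0%, T-like cells at 1.91% and 6.22%, and unnamed cells at 38.0% and 16.9%.

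Over all kept cells together, the alarmins S100a8 and S100a9 stood at 5048.7 and 4703.8 CPM in WT and at 177 and 189 CPM in KO. Krt6b, a keratin of wounded epidermis, was 35.7-fold lower in KO (33.0 to 38.7), and Chil3, a chitinase-like protein of myeloid cells, 190-fold lower (137 to 273). Sprr2d was 17.5-fold lower (16.7 to 18.3). Dapl1 was 8.51-fold higher in KO (8.15 to 8.90), Fmod 6.38-fold (6.05 to 6.74), Iigp1 5.47-fold (5.17 to 5.79), Cldn3 5.01-fold (4.74 to 5.30) and Rsad2 4.12-fold (3.92 to 4.34). Of 34 lists with a median, 8 were called higher and 11 lower. These values mix expression with the class shares. A median-ratio scale differed from the total-count scale by 0.12 log2 over all cells, 0.10 in fibroblast-like cells and 0.13 in T-like cells, and it turned no called list.

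In keratinocyte-like cells (3888 WT and 2662 KO cells), genes of the inflamed epidermis were lower in the KO library. S100a8 (chromosome 3, 90668978 to 90670035) stood at 7723.4 CPM in WT and 334 CPM in KO, 23.1-fold lower (22.8 to 23.4), and S100a9 was 20.3-fold lower (20.01 to 20.56). Krt6b was 28.6-fold lower (26.4 to 31.0), Gsta4 14.5-fold (12.96 to 16.33) and Sprr2d 13.7-fold (13.1 to 14.3). Sprr2e, Sprr2i, Lce3d, Lce3c and Il1f6, an IL-36 family cytokine, were lower by 9.67-, 8.84-, 8.84-, 7.19- and 6.66-fold. Higher in KO were Dapl1 (10.4-fold, 9.91 to 10.9), the cornified envelope protein gene Lor (8.71-fold, 7.99 to 9.50), Pkib (7.12-fold), the suprabasal keratin Krt77 (6.56-fold) and the transcription regulators Id1 (3.80-fold) and Id4 (3.58-fold). The immediate early gene Egr1, the heat shock gene Hspa1b, Zfp36l1 and Tchh were higher by 3.34-, 3.098-, 3.104- and 3.13-fold.

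IL-17 and TNF response genes had a median log2 ratio of -1.91 (-2.13 to -1.74, percentile 0), with 16 of 21 measured members lower and 3 higher. S100a8 had both the highest level and the lowest ratio, and Cxcl1, a neutrophil chemokine, was the most raised member (87.0 and 162 CPM). Ccl20 (782 and 1179.7 CPM) and Nfkbiz (209 and 333 CPM), named outside the rule, were the other raised members. Without members that could be free RNA, 8 of 11 were lower and 2 higher. Antimicrobial and alarmin genes had a median of -1.30, with 12 of 17 lower, while Defb1 was 2.24-fold higher. Wound and hyperproliferation keratins and partners had a median of -1.08, with 9 of 14 lower. Their most abundant member, Krt17, was at 4220.8 and 4955.8 CPM, and Sprr1a was 1.43-fold higher. Proinflammatory cytokines had a median of -0.40 with 7 of 16 lower. There Il33 was 0.253 times its WT level, Tslp, the most abundant, 0.499 times and Il10 7.80 times. Hypoxia and glycolysis genes had a median of -0.39, with 8 of 20 lower, among them Gapdh (0.511 times) and Eno1 (0.443 times), and Egln3 was 1.83 times its WT level.

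Cornified envelope and barrier genes had a median of 0.86 (percentile 100), with 13 of 22 higher and 3 lower. Klk7, a protease of corneocyte shedding, was the most abundant (508 and 655 CPM), Lce1a1 the most raised (0.141 and 10.3 CPM), and Lce3c the most lowered. Immediate early genes had a median of 0.93 with 14 of 18 higher, heat shock genes 0.69 with 8 of 14 higher, and EGFR ligand and AP-1 genes 0.39 with 8 of 22 higher. Jun stood at 1112.9 and 2185.5 CPM, Jund was 1.31-fold higher, Fos 2.68-fold and Egfr 0.762 times. Hspa1a was 4.48-fold higher, the abundant Hsp90ab1 1.15-fold and Hspa4l 1.07-fold. STAT3 targets and JAK-STAT feedback genes had a median of 0.43 with 7 of 22 higher, among them Cish (2.56-fold) and Junb (1.88-fold), while Il4ra was 0.686 times its WT level. Of the list members named so far in this class, Cxcl1 and Hspa1a could be free RNA. Of 34 lists with a median, 8 were called higher and 15 lower, of which 6 and 9 were also called without possible free RNA.

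G2 and M phase genes had a keratinocyte median of -0.74 with 18 of 28 lower, from Aurkb (0.355 times) to Cks2 (1.06 times) and with Hmgb2 most abundant (0.967 times), and S phase genes -0.47 with 11 of 24 lower, from Mcm2 (0.397 times) to Slbp (1.66 times). After thinning, Mki67 or Top2a was seen in 3.101% (2.58 to 3.70) of WT and 2.07% (1.56 to 2.68) of KO keratinocyte-like cells, and unthinned in 26.7% and 25.02%. In fibroblast-like cells, taken as a background, the thinned shares were 0.364% and 0.141%. Median depths were 14047.5 and 17648.5 UMIs in keratinocyte-like cells and 7349 and 6404 in fibroblast-like cells. Basal epidermal genes had a median of -0.28 with 5 of 16 lower. Krt14, the most abundant, was at 0.613 times its WT level, Krt5 at 0.454 and Krt15 at 1.45 times. Suprabasal genes had a median of 0.31 with 4 of 16 higher, Mt4 at 6.07, Calml3 at 0.722 and the abundant Lgals7 at 0.926 times the WT level.

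The 6 keratinocyte-like clusters were unevenly filled, with 431 WT and 0 KO cells in cluster 6, 675 and 129 in cluster 10, 1198 and 208 in cluster 19, 599 and 1027 in cluster 11, 681 and 689 in cluster 12, and 304 and 609 in cluster 18. Krt15 and Col17a1 were among the leading genes of clusters 18 and 19. So were members of the hair follicle list, Lhx2 in cluster 18 and Sox9 in cluster 19. The class values may therefore include hair follicle cells, which were not separated. In clusters with at least 20% of cells from each library the G2 and M phase median was 0.29, the S phase median 0.26, the basal median 0.61, the proinflammatory cytokine median 0.22 and the suprabasal median -0.28, each of the opposite sign. Interferon-stimulated genes, at 0.64 with 12 of 25 higher (Ifi27l2a 6.32-fold, Oas1a 0.751 times and the abundant Ifitm3 0.979 times), went to -0.27 in thinned cells, and 23 of the 25 could be free RNA. Within clusters 11, 12, 18 and 19 the median of the IL-17 and TNF response genes lay between -2.25 and -0.68. Markers of some other cell types also fell in keratinocyte-like cells, erythroid ones from 164 to 19.4 CPM (0.118 times), dendritic ones to 0.429, fibroblast ones to 0.557 and monocyte and macrophage ones to 0.602 times, while T cell markers were 1.36 times their WT level. Hair follicle and sebaceous gland markers rose from 6718.0 to 8941.6 CPM (1.33 times), and hair follicle genes were called higher, at 0.34 with 5 of 14 higher and 4 lower. Without members that could be free RNA the hair follicle list was not called (0.34 over 12 members, percentile 95.95).

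**Figure D2:**
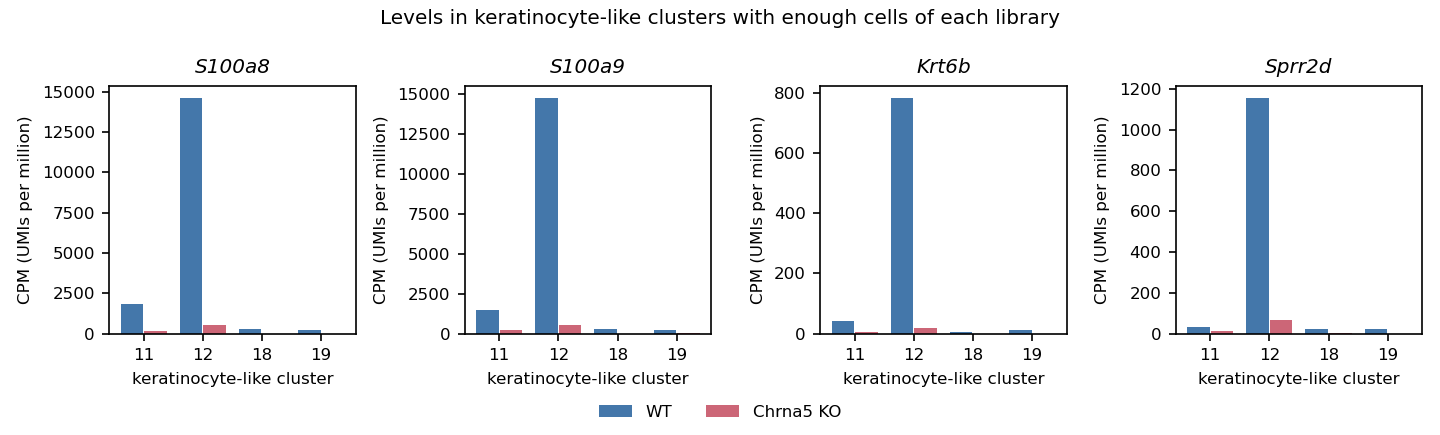
CPM of S100a8, S100a9, Krt6b and Sprr2d in the 4 keratinocyte-like clusters with at least 200 cells of each library, for the WT (blue) and Chrna5 KO (red) library. Each bar is 1 pooled sum, and in cluster 12 the WT level of S100a8 is 14626.8 CPM.

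**Figure D3:**
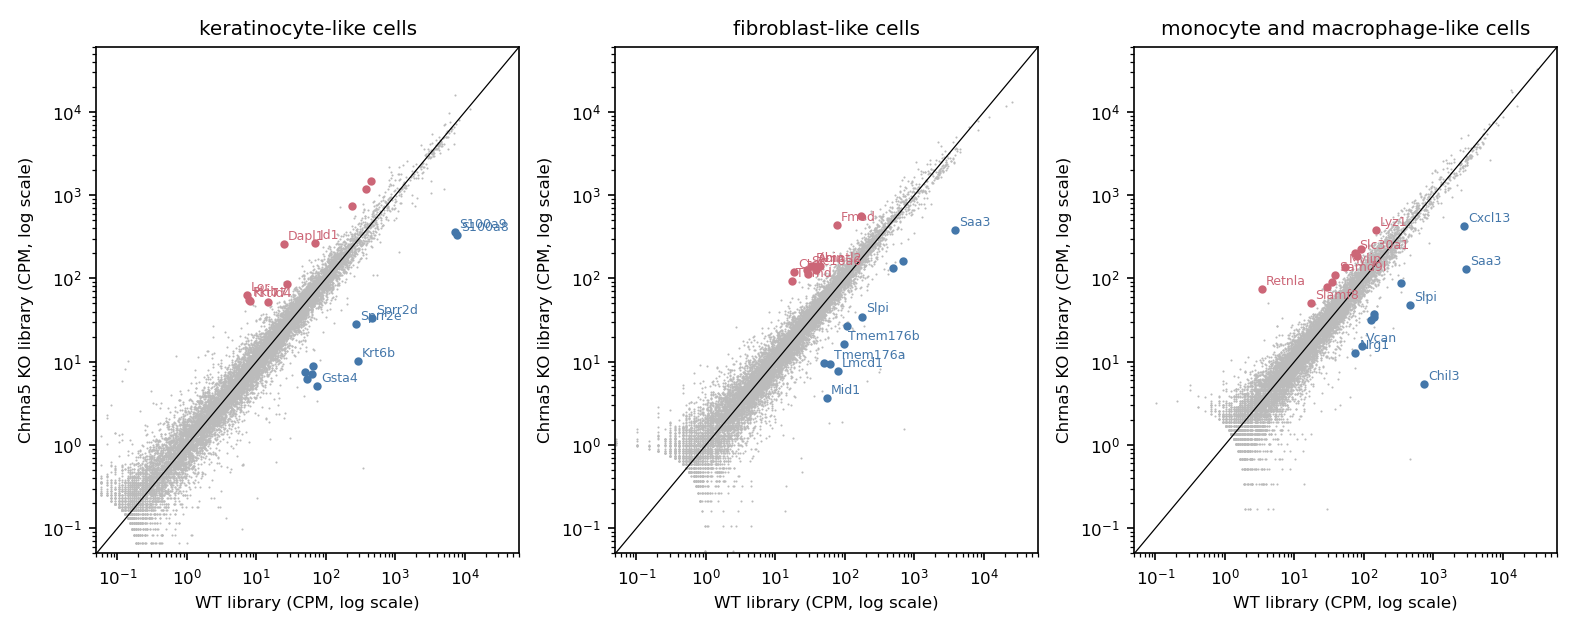
CPM of each gene in the WT library (x, log scale) and the Chrna5 KO library (y, log scale) in the 3 largest classes, with the line of equal levels. Named genes are red where higher and blue where lower in KO, such as Krt6b at 288 and 10.1 CPM in keratinocyte-like cells.

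In fibroblast-like cells (2473 WT and 2849 KO cells), Saa3 and C3 were among the genes lower in the KO library, and Ctgf, Fmod and Tnmd among those higher. Saa3, an acute phase protein gene (chromosome 7, 46711998 to 46715700), stood at 3860.8 CPM in WT and 376 CPM in KO, 10.3-fold lower (10.01 to 10.51). Complement C3 was 3.68-fold lower (3.52 to 3.85), the prostaglandin E synthase Ptges 4.22-fold (4.06 to 4.40) and the protease inhibitor Slpi 5.09-fold (4.68 to 5.55). Mid1, Lmcd1, Tmem176a, Tmem176b, Serpina3f and Cyp7b1 were lower by 15.2-, 10.3-, 6.40-, 5.96-, 5.24- and 4.03-fold. Ctgf, a matricellular growth factor gene, was 6.43-fold higher (5.75 to 7.199), the small proteoglycan Fmod 5.70-fold (5.39 to 6.02), Tnmd 5.39-fold and Aspn 3.28-fold. Slc16a6, Fibin, Amotl2, the EGFR ligand Ereg, Gldn and Arl6ip5 were higher by 4.43-, 4.26-, 3.86-, 3.85-, 3.29- and 3.25-fold.

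Interferon-stimulated genes had a fibroblast median of 0.92 (0.81 to 1.12) with 15 of 22 higher, Ifit2 5.26-fold and the abundant Ifitm3 1.30-fold, while Cxcl10 was 0.762 times its WT level. All but 3 of the 22 could be free RNA, too few for a median without them. Immediate early genes had a median of 0.62 with 9 of 18 higher (Egr1 2.36-fold, Atf3 1.14-fold) and heat shock genes 0.63 with 8 of 14 higher (Hspa1b 2.68-fold, Hspb1 1.23-fold and the abundant Hsp90aa1 1.65-fold). STAT3 targets had a median of 0.32 with 5 of 22 higher, Pim1 2.28-fold and the abundant Cebpb 1.40-fold, while Timp1 was 0.354 times its WT level. Fibrillar collagens and matrix genes were not called, with a median of 0.13 and 7 of 22 higher, Fn1 at 2.66, the abundant Dcn at 0.733 and Lum at 0.681 times the WT level. In all, 4 lists were called higher and 16 lower, and 3 of each were also called once members that could be free RNA were left out. The lower ones were IL-17 and TNF response genes (-1.95 with all 19 measured members, -0.56 with 8), neutrophil and monocyte chemokines (-0.86 and -0.30) and matrix proteases and inhibitors (-0.42 and -0.28). Among them Lcn2 was 0.0194 times, Cxcl3 0.0694 times and Mmp12 0.0974 times the WT level, while Nfkbiz was 1.40-fold, Cxcl1 1.11-fold and Timp3 1.74-fold higher. Of the members named here, Lcn2, Cxcl3, Mmp12, Timp3 and Hspb1 could also be free RNA. The most abundant members, Ccl2 and Mmp2, were at 0.945 and 0.768 times. Keratinocyte genes also fell in this class, wound keratins with a median of -1.80 and suprabasal genes with -0.87. The largest cluster of fibroblast-like cells was cluster 14 in WT (1496 WT and 220 KO cells) and cluster 15 in KO (187 and 1232). The others held 495 and 495 in cluster 16, 191 and 486 in cluster 17, and 104 and 416 in cluster 30. Fmod, Aspn, Tnmd and Gldn were among the leading genes of cluster 30.

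In monocyte and macrophage-like cells (1126 WT and 880 KO cells), Chil3 and Il1b were lower and MHC class II genes higher in the KO library. Chil3 fell from 741 CPM in WT to 5.42 CPM in KO, 137-fold lower (96.7 to 200). Saa3 was 22.9-fold lower (21.3 to 24.6), Slpi 9.79-fold (8.67 to 11.1), the B cell chemokine Cxcl13 6.50-fold (6.24 to 6.78) and the cytokine Il1b 3.92-fold (3.57 to 4.30). Vcan, Nrg1, Inhba, Cd72 and Slc13a3 were lower by 6.11-, 5.89-, 4.10-, 4.02- and 3.70-fold. Retnla, a gene of alternatively activated macrophages, stood at 3.43 and 75.1 CPM, 21.9-fold higher (15.4 to 32.2). Chil3 is in the same list of alternative macrophage activation genes and went the other way. Without members that could be free RNA, that list had a median of 0.33 (percentile 97.64), with 4 of 12 higher and 1 lower. The interferon-induced genes Samd9l, Ifi27l2a and Oasl1 were higher by 2.81-, 2.51- and 2.38-fold, and Slc30a1, Lyz1, Slamf8, Mylip, Ptbp1 and Elmsan1 by 2.71-, 2.60-, 2.88-, 2.59-, 2.69- and 2.60-fold.

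Interferon-stimulated genes had a median of 0.83 (0.61 to 0.99) with 15 of 26 higher and 2 lower, Cxcl9 being 5.07-fold higher, Cxcl10 0.431 times and the abundant Ifitm3 0.595 times. MHC class II genes had a median of 0.73 with 5 of 11 higher. Cd74, the invariant chain, was at 3142.8 and 5205.6 CPM, Ciita was 2.96-fold higher (1.55 to 5.83) and Cd80 0.851 times (0.556 to 1.28). MHC class I genes had a median of 0.39 with 3 of 16 higher, H2-T23 1.94-fold, B2m, the most abundant, 1.47-fold and Psmb8 0.805 times. NF-kB targets had a median of -0.32 with 6 of 21 lower and Nfkbia, the most abundant, at 0.748 times, while Tnfaip3 was 1.15-fold higher. Neutrophil and monocyte chemokines had a median of -0.54 with 7 of 15 lower, Cxcl2 at 6488.8 and 2604.1 CPM, Ccl12 0.398 times and Ccl7 1.02 times. In all, 5 lists were called higher and 16 lower, and 4 of the higher and 5 of the lower calls were also made without possible free RNA, with an IL-17 and TNF response median of -1.14 against -2.13. Of the members named here, Cxcl9, Cxcl10, Ifitm3, Ciita, Cd80 and Nfkbia could be free RNA. Keratinocyte markers in this class fell from 2885.0 to 845.5 CPM (0.293 times, 0.284 to 0.302) and fibroblast markers to 0.673 times, while T cell markers rose from 23.3 to 59.7 CPM (2.57 times), and so did markers of other antigen-presenting cells, dendritic ones from 89.1 to 124 CPM (1.39 times, 1.26 to 1.54) and Langerhans ones 1.23 times. Cluster 8, which Chil3, Lyz2, Ccl3 and Il1b lead, held 184 WT and 10 KO cells, beside 584 and 507 in cluster 0 and 358 and 363 in cluster 1.

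**Figure D4:**
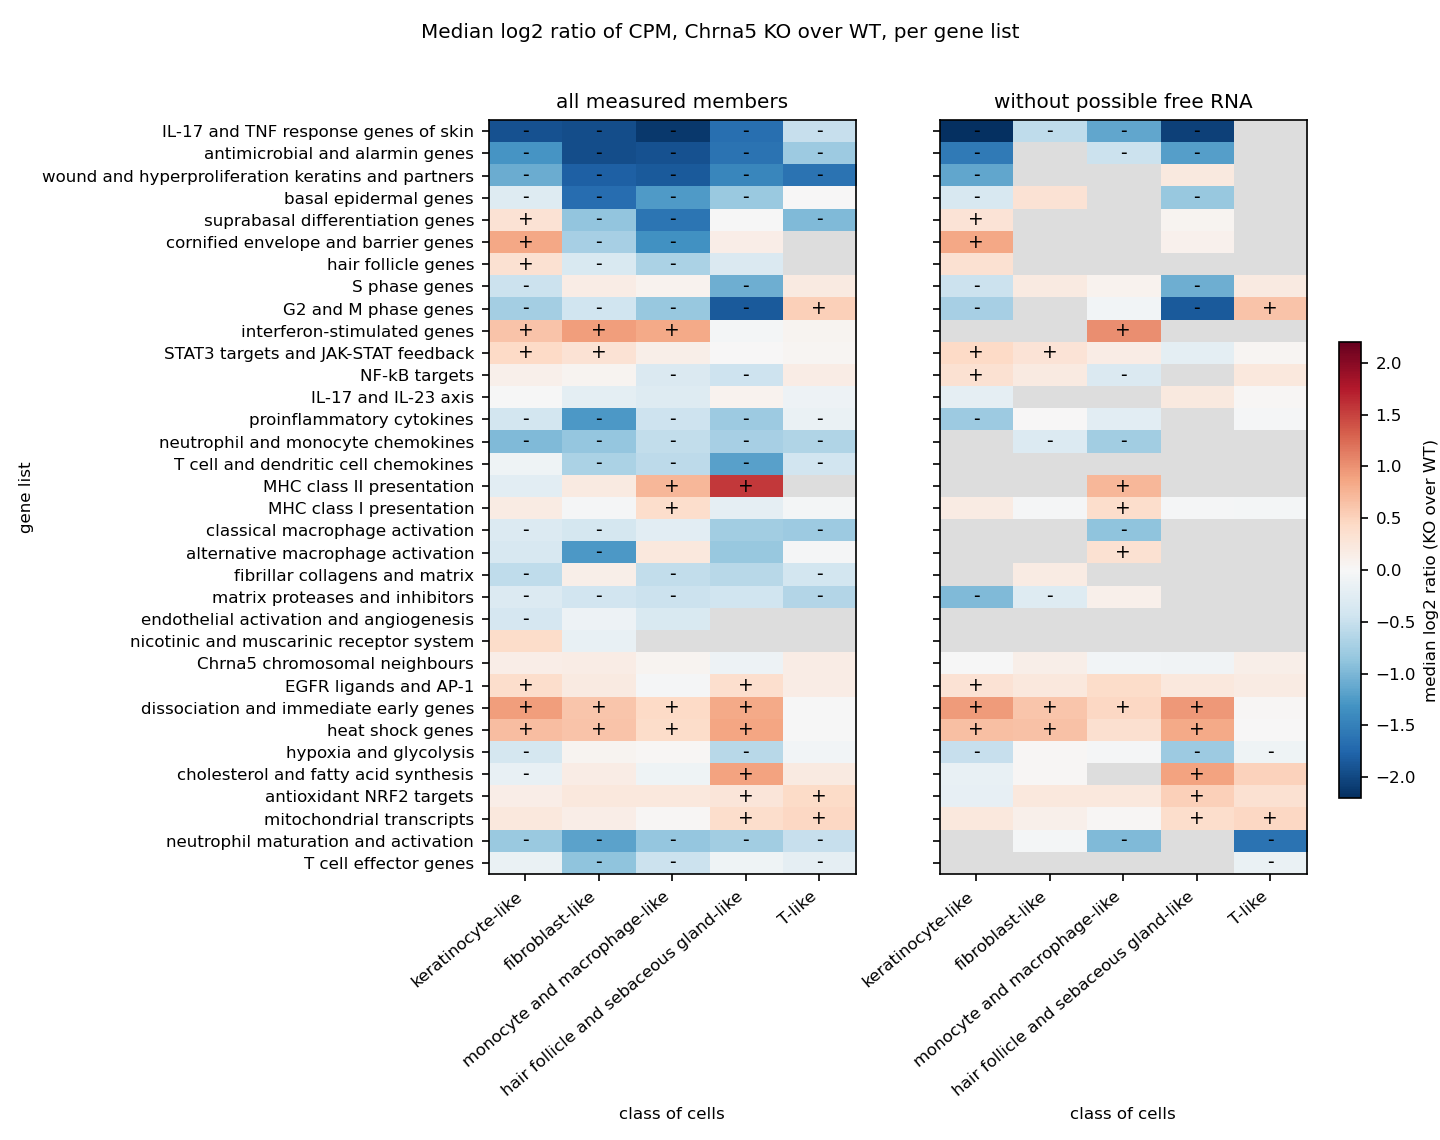
Median log2 ratio of CPM (KO over WT, colour) for each gene list and class, over all measured members and without members that could be free RNA. Plus and minus signs mark lists called higher or lower, and grey marks fewer than 5 measured members, as for interferon-stimulated genes in keratinocyte-like cells on the right.

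Hair follicle and sebaceous gland-like cells (335 WT and 296 KO cells) formed 1 cluster, led by lipid synthesis genes, in which such genes were higher in the KO library. Cholesterol and fatty acid synthesis genes had a median of 0.89 with 14 of 20 higher. The desaturase Scd1 stood at 1832.7 and 4334.6 CPM, the elongase Elovl6 was 4.46-fold higher (4.32 to 4.60), and Scd2, which could be free RNA, was 0.673 times its WT level. Elovl5, Serpina3j, Rarres1 and Tmem159 were higher by 5.20-, 5.23-, 4.12- and 4.19-fold. S100a8 was 134-fold lower (112 to 161), Il1f9, the gene of IL-36 gamma, 9.28-fold, Orm1 6.85-fold and the basal keratin Krt5 6.79-fold. Other lists were also called here without members that could be free RNA, each with 0 members the other way. Basal epidermal genes had a median of -0.84 (8 of 13 lower) and mitochondrial transcripts 0.39 (2 of 13 higher). Immediate early genes had 0.95 (6 of 6 higher) and heat shock genes 0.83 (7 of 11 higher). G2 and M phase genes had a median of -1.85 with 28 of 28 lower (Aurkb 0.112, Cks2 0.653 and the abundant Hmgb2 0.597 times), and S phase genes -1.07 with 14 of 24 lower (Clspn 0.209, Ccne2 1.56 and the abundant Pcna 1.00 times). With each library clustered on its own these became 0.40 and 0.09, so the direction rests on which cells the class holds. MHC class II genes had a median of 1.55 over 7 members, all of which could be free RNA in this class, with Cd74 at 5.37, H2-Aa at 7.50 and Cd40 at 0.268 times.

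In T-like cells (266 WT and 633 KO cells), the effector cytokine gene Il22 (chromosome 10, 118204942 to 118210047) stood at 526 CPM in WT and 85.6 CPM in KO, 6.14-fold lower (5.24 to 7.21). T cell effector genes had a median of -0.20 (percentile 0.0400), with 6 of 20 lower and 1 higher. Gzmb, the granzyme B gene and most abundant member, was 0.450 times its WT level (0.415 to 0.488). Il17a went the other way, at 79.8 and 129 CPM, 1.62-fold higher (1.27 to 2.08), and Il17f, named after its value was seen, was 0.298 times its WT level (0.248 to 0.359). Mmp12, Cxcl3, Ly6a and Ramp1 were lower by 38.0-, 5.53-, 5.27- and 4.98-fold. Keratinocyte genes also fell in this class, wound keratins with a median of -1.62 (9 of 12 lower) and suprabasal genes with -0.96 (7 of 10 lower). Igf1r, Tulp4, Kcnq1ot1, Ttc28 and Ptbp1 were higher by 3.19-, 2.75-, 2.83-, 3.38- and 2.42-fold. Mitochondrial transcripts had a median of 0.46 with 4 of 13 higher (mt-Co3 1.72, mt-Atp8 0.726 and the abundant mt-Atp6 1.40 times). NRF2 targets had 0.42 with 1 of 14 higher (Slc7a11 1.75, Gstp1 0.293 and the abundant Txn1 1.27 times), Slc7a11 being possible free RNA. G2 and M phase genes had a median of 0.52 with 4 of 13 higher (Nusap1 4.34, Birc5 0.610 and the abundant Hmgb2 1.18 times; Birc5 could be free RNA), whereas the thinned share of cycling cells was 2.26% (0.835 to 4.86) in WT and 1.74% (0.873 to 3.098) in KO, so no order is read from it. Of 29 lists with a median, 3 were called higher and 12 lower, but without members that could be free RNA only 2 of each were also called, and NRF2 targets, at 0.34, were not. Cluster 21 held 186 WT and 470 KO cells, and cluster 32, led by the gamma delta T cell genes Trdc and Trdv4, 80 and 163.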

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

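The tests of the barcodes of mixed profile were chosen only after their result was seen. G2 and M phase genes moved in opposite directions between classes. Their median log2 ratio of KO over WT was -0.742 in keratinocyte-like cells and -1.85 in hair follicle and sebaceous gland-like cells, and 0.519 in T-like cells. The difference between classes was not tested, and no explanation was weighed. The opposition does not hold under every alternative: the keratinocyte median was 0.289 in clusters with at least 20% of cells from each library, and the hair follicle and sebaceous gland median 0.399 with each library clustered on its own.

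Cells in clusters without a name made up 38.0% of the WT and 16.9% of the KO library, and the comparisons of gene levels within classes do not use them, while the shares of all kept cells count them in the total. In the WT library, 5 such clusters with a mixed profile held 4419 cells (31.7% of the library) with a median of 1112 UMIs, against 8426.5 in named cells. Doublets would hold more RNA than single cells, yet their median depth was 13.2% of that of named cells, which argues against doublets. Free RNA in barcodes with little RNA of their own may explain them, but its test cannot decide this. Summed keratinocyte, fibroblast and macrophage markers lay within 0.401 log2 of their level in the whole library, where up to 1 was allowed. The sums pool 5 clusters whose leading genes differ, such as Ctsk and Mmp2 in cluster 4 and Sprr2d in cluster 3. A pool of shallow cells of several types would also lie near the library level. Clusters 13 (49 WT and 737 KO cells, median 1113.5 UMIs), 29 (46 and 165) and 34 (0 and 135) also had a mixed profile. They held mostly KO cells and were in neither test. No biological explanation was tested.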

How the results depend on the processing

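The alternatives with at least 1000 UMIs, without the highest doublet scores, with shares of named cells, with clusters holding at least 20% of cells from each library, and without members that could be free RNA were chosen only after the results were seen. No paired analysis was possible with 1 library per genotype. Over alternatives with a value, the cycling share of all kept cells, which clustering cannot change, kept its direction in 10 of 10. The 90 gene ratios the rule picked for being far from 1 kept theirs in 1030 of 1030, which tests little. Their size moved for 68 in thinned cells, 54 with equal cell weight and 42 of 80 in the clusters of at least 20%. Of list medians, 86 moved without turning in thinned cells, 62 under median-ratio scaling and 48 with separate clustering. Medians of 117 called lists turned in 35 of 1451. The 10 shares whose ratio bounds left out 1 turned in 5 of 85, each the keratinocyte share. Thinning drops and reweights cells too, so cannot isolate depth. Called values that turned follow, with moved list counts and 4 class shares. The cause was not tested. With at least 1000 UMIs, fibrillar collagens in T-like cells went from -0.401 to 0.155 and the fibroblast share from 1.58 to 1.43; with at least 500 genes to 0.143 and 1.44. In thinned cells, NF-kB targets in hair follicle and sebaceous gland-like cells went from -0.459 to 0.124, cornified envelope and barrier genes in all kept cells, median log2 ratio, from 0.567 to -0.182, interferon-stimulated genes in keratinocyte, median log2 ratio, from 0.636 to -0.266, neutrophil maturation genes in fibroblast-like cells from -1.18 to 0.217, and the lists lower in fibroblast-like cells from 16 to 9. At resolution 0.5, T cell and dendritic cell chemokines in monocyte and macrophage, median log2 ratio, went from -0.580 to 0.0190 and the keratinocyte share from 0.937 to 1.06. At resolution 2, hair follicle genes in fibroblast-like cells went from -0.329 to 0.0952 and the keratinocyte share to 1.04. In the clusters of at least 20%, lists in keratinocyte-like cells turned: G2 and M phase to 0.289, S phase from -0.467 to 0.262, basal from -0.276 to 0.608, classical activation from -0.299 to 0.201, endothelial activation from -0.374 to 0.461, collagens from -0.567 to 0.319, matrix proteases from -0.303 to 0.174, proinflammatory cytokines in keratinocyte, median log2 ratio, from -0.400 to 0.215 and suprabasal differentiation genes in keratinocyte, median log2 ratio, from 0.313 to -0.283. Lists lower there went from 15 to 8, and lists higher in fibroblast-like cells from 4 to 2. With each library clustered on its own, G2 and M phase genes in hair follicle and sebaceous gland-like cells went to 0.399 and S phase genes from -1.07 to 0.0921. In keratinocyte-like cells basal genes went to 0.316, endothelial activation to 0.263, collagens to 0.110, proinflammatory cytokines to 0.00745, suprabasal genes to -0.0619 and lower lists to 9. The keratinocyte share went to 1.45 and the share of monocyte and macrophage cells, KO over WT, from 1.07 to 0.843. Without the highest doublet scores, T cell and dendritic cell chemokines in monocyte and macrophage-like cells went to 0.0243, lower lists there from 16 to 10 and the keratinocyte share to 1.05. Without members that could be free RNA, basal genes in fibroblast-like cells went from -1.67 to 0.320, proinflammatory cytokines there from -1.27 to 0.00795, matrix proteases in monocyte and macrophage-like cells from -0.479 to 0.104 and wound keratins in hair follicle and sebaceous gland-like cells from -1.44 to 0.213; lower lists went to 3 in fibroblast-like, 9 in keratinocyte-like and 6 in monocyte and macrophage-like cells. With members of at least 1 UMI, T cell effector genes in fibroblast-like cells went from -0.885 to 0.207. With a mitochondrial limit of 20%, cholesterol synthesis genes in keratinocyte-like cells went from -0.161 to 0.0369, hair follicle genes in fibroblast-like cells to 0.126 and the keratinocyte share to 0.797. With no doublets removed, endothelial activation in keratinocyte-like cells went to 0.355, fibrillar collagens and matrix in monocyte and macrophage, median log2 ratio, from -0.548 to 0.0690, hair follicle genes in fibroblast-like cells to 0.158 and the keratinocyte share to 1.04. As shares of named cells, T-like cells went from 3.26 to 2.43, fibroblast-like to 1.18, keratinocyte-like to 0.699 and monocyte and macrophage-like to 0.798.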

Other observations

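The tests of the IL-17 and TNF response genes and the cluster test of the immediate early and heat shock genes were chosen only after related results were seen, that of different clusters as the whole difference, with its bound of 0, after the cluster medians themselves, and the test of handling before. Classes with fewer than 200 cells in a library are given as values alone. In vascular endothelial-like cells, interferon-stimulated genes had a median log2 ratio of 1.49 with 22 of 26 higher in KO, MHC class I genes 0.61 with 9 of 16 higher, and endothelial activation genes -0.48. Interferon-stimulated genes had a median of 1.12 in Schwann-like cells (8 of 16 higher) and 0.99 in pericyte and smooth muscle-like cells (6 of 17 higher). They were not called in Langerhans-like (0.45, 2 of 5 higher and 1 lower), lymphatic endothelial-like (0.34, 2 of 18 higher and 4 lower), melanocyte-like (0.02, 0 of 5 higher), T-like (0.07, 0 of 13 higher) or hair follicle and sebaceous gland-like cells (-0.05, 5 of 14 higher and 3 lower). Endothelial activation genes had a median of -0.64 in pericyte and smooth muscle-like cells and -0.54 in lymphatic endothelial-like cells. In Langerhans-like cells MHC class II genes had a median of -0.61, with 5 of 11 lower. Free RNA was not assessed in the smaller classes. Both keratinocyte lists, wound keratins and suprabasal genes, were called lower in 6 of these 7, with medians of -2.34 and -2.08 in vascular endothelial-like, -1.90 and -2.08 in lymphatic endothelial-like, -1.37 and -0.92 in pericyte and smooth muscle-like and -0.55 and -0.55 in Schwann-like cells. Among unnamed clusters, one led by Serpine2, Crabp1, Lef1 and Rspo3 held 635 WT and 354 KO cells, and one led by Wfdc18, Cldn3 and Krt75 held 145 and 223.

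IL-17 and TNF response genes were lower in keratinocyte-like cells of the KO library. Free RNA of the WT library as the whole cause is argued against, as their WT CPM was higher in the deepest than in the shallowest of 4 keratinocyte-like clusters, by a median of 2.78 log2 with 16 of 20 members higher, where a shared background gives at most 0. In the shallower clusters 18 and 19, the WT level of S100a8 (265 and 253 CPM) was near that in fibroblast-like cells (308 CPM), so free RNA stays open there. Different clusters as the whole difference were weighed with a bound set after the cluster medians were seen, so its outcome decides nothing. The 4 medians lay from -2.25 to -0.677. The upper ends of their counting intervals were at most -0.359, in cluster 19, where free RNA stays open. In cluster 12 (681 WT and 689 KO cells) the median was -2.25 (-2.39 to -2.12) and S100a8 was 26.6-fold lower. The difference within cluster 12, the lowest of the 4 medians, was not one of cluster membership at this resolution. A cluster can still hold different cells of each library, so no verdict is drawn from it. Clusters 6 (431 WT and 0 KO cells) and 10 (675 and 129) were in no test. Different clusters as most of the difference cannot be told apart from a change within clusters, since the highest median of -0.677 lay between the bounds of -0.5 and -1, and the genotype stays an untested hypothesis.

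Immediate early and heat shock genes were higher in the KO library. Different clusters as the whole cause are argued against, since within 9 named clusters with at least 200 cells of each library their joint median had a median of 0.494 and was above 0.2 in 8, from -0.086 to 0.857. Handling of the whole sample may be the cause: in 5 of 7 smaller classes the joint median lay above 0.3, between the bounds of 6 and 3 classes. The median mitochondrial share of kept cells was 1.86% in WT and 2.42% in KO, while mitochondrial transcripts over all kept cells were not called (0.12). Handling and genotype cannot be told apart, since each genotype is 1 library. The joint median did not reach 0.3 in Schwann-like (0.22) and melanocyte-like (0.14) cells, and both lists lay near 0 in T-like cells (-0.01 and -0.01).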
